A study of Mus musculus with 6 samples.

How the data were processed

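Small RNA libraries of large and small extracellular vesicles from mouse bone, 3 of each, were compared. Per the labels' protocols, RNA was extracted with a miRNeasy kit, libraries were made with the QIAseq miRNA kit and sequenced on an Illumina MiSeq as single reads of 75 bases. The authors deposited counts per mature miRNA and library, whole numbers that are not normalized. Per the submitters' processing notes, the genome build was GRCm38, and R 4.2.2 and DESeq2 1.38.2 were used. The aligner, the way reads were assigned to miRNAs, the use of strand, and whether reads or unique molecular identifiers were counted are not given in the sources used here. The QIAseq kit adds molecular identifiers, so the counts may be of either kind. If strand was ignored, reads of a hairpin and of a gene antisense to it, such as Mir434 and Rtl1 or Mir5126 and Dner, may have been counted together. Of the 1927 rows, 35 joined the names of miRNAs with a slash, which held between 12.0% and 13.2% of the counts of a library. Across the 6 libraries the table had 0 values of 1 and 77 values of 2, so a value of 0 may stand for 0 or 1 count, and no upper limit was derived from zeros.

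Columns were assigned to libraries by the labels, and groups and replicate numbers were taken from the sample titles. All fold changes are sEVs relative to lEVs. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with its defaults of at least 10 counts and a total of at least 15), which kept 145 of the 327 miRNAs above 0 in any library. The tested miRNAs held between 99.4% and 99.6% of the counts of each library. P-values were adjusted by Benjamini-Hochberg over the miRNAs tested and called at 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. TMM factors were 0.853, 1.18 and 1.12 for lEVs replicates 1, 2 and 3, and 0.960, 0.952 and 0.974 for sEVs replicates 1, 2 and 3. The common biological coefficient of variation was 0.177, and 0.0832 without lEVs replicate 1. Abundances are given as CPM with TMM factors, mean ± SD over 3 libraries. Log2 differences of lEVs replicate 1 from the other lEVs libraries also use CPM with TMM factors. Its factor of 0.853, against 1.18 and 1.12, raises these differences relative to shares of library totals.

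Before the data were examined, 16 lists of miRNAs were fixed: erythroid, myeloid, lymphoid, skeletal muscle, endothelial, mesenchymal, osteoblast-associated, cartilage, liver and kidney, neural and epithelial markers, the let-7 family and its passenger strands, the miR-30 family, the miR-17-92 and paralogous clusters, and the Dlk1-Dio3 cluster. The 11 lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera under an estimated correlation, and with fry. Lists defined by motifs in the mature sequence were not used here. The main tests, the other alternatives and the naming rule were also fixed before the data were examined. The alternatives that read every 0 as 1 count or recomputed the ratios between miRNAs were chosen after seeing the data. So were the tests of the splits, of the depth and label of lEVs replicate 1, and of ratios between arms and between neighbouring miRNAs. By the naming rule the text named the 10 miRNAs with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 100 CPM and with the 3 values of one fraction above those of the other. It also named the 5 most abundant miRNAs of each fraction and up to 4 of the most abundant tested members of each list, 64 miRNAs in all.

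Numbers of detected miRNAs were counted after thinning each library to 47441 counts, as the mean of 20 draws. Differences of single values between fractions were tested with exact two-sided permutation tests, in which 3 against 3 libraries give p = 0.1 at the lowest. Replicates were compared by chi-square tests of their counts; within a fraction the statistic over its degrees of freedom ranged from 2.40 to 25.2, so no libraries were near-duplicates. Hairpin positions were taken from the GENCODE M21 annotation of GRCm38, matched by gene symbols and synonyms, with 168 of the 168 miRNAs looked up found. Stretches of 20 bases shared with other genes were searched in the transcripts of that annotation. The search covered whole hairpins, so a shared stretch need not lie in the mature arm. Ratios between miRNAs within a library were tested with limma on log2 values with a pseudocount of 10 CPM, and again with library totals, a pseudocount of 1 CPM and each library left out. Rank correlations across miRNAs used 100000 permutations.

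Alternatives were DESeq2 1.42.0, limma voom, DESeq2 size factors in edgeR, library totals, no filter on low counts, a mean of at least 100 CPM, the replicate number as a block, thinned libraries, leaving out the 5 most abundant miRNAs, and leaving out each library in turn. The edgeR step was tested on simulated data with the abundances, depths and dispersions of these libraries, with 40 of 145 miRNAs changed in each of 20 simulations. It called 35.0% of the miRNAs changed 1.5-fold, 71.5% of those changed 2-fold and 98.1% of those changed 4-fold, and 1.10% of the unchanged ones; 4.09% of its calls were false. In the same step, camera gave p under 0.05 for 20 of 20 simulated lists of 8 miRNAs shifted 1.5-fold and for 1 of 20 unshifted lists. Only abundances, depths and dispersions were taken from the libraries, so this does not check the preset correlation between miRNAs. Nor does it hold 1 library that stands apart from its fraction, as lEVs replicate 1 did, so these rates may differ for the real data. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.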

Results

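Small RNA was sequenced from extracellular vesicles (EVs), the membrane-bound particles that cells release, collected from crushed long bones of the hind leg (tibia and femur) of male Swiss-CD1 mice aged 8 weeks, after the marrow had been spun out. Vesicles were separated by centrifugation into large EVs (lEVs), the pellet of a spin at 10000 g, and small EVs (sEVs), which were collected at 100000 g on a 30% sucrose cushion. The data were 3 libraries of each fraction, with counts for 1927 mature microRNAs (miRNAs), the short RNAs that guide silencing of matching messenger RNAs. The libraries of lEVs replicates 1, 2 and 3 held 47441, 92502 and 86637 counts, and those of sEVs replicates 1, 2 and 3 held 75486, 99314 and 114331 counts. In the same order, 194, 245 and 235 miRNAs were above 0 in the lEVs libraries and 202, 224 and 239 in the sEVs libraries. The labels do not say whether replicates came from separate animals or preparations, so the p-values measure only the spread between these samples, which may be technical.

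Both fractions were dominated by the same few miRNAs. In CPM (counts scaled to a common library size) with TMM factors, miR-16-5p, abundant in blood cells, was highest at 151643 ± 6836 CPM in sEVs and 167642 ± 42934 CPM in lEVs (SD, n = 3 each). It was followed in both fractions by the joined row miR-199a-3p/199b-3p (97229 ± 5976 CPM in sEVs and 90265 ± 15722 CPM in lEVs), let-7c-5p (84432 ± 5785 and 72392 ± 27954 CPM) and miR-126a-3p (77731 ± 3438 and 63178 ± 6408 CPM). The spread in lEVs depended on the TMM factors. As shares of library totals, miR-199a-3p/199b-3p held 9.36% ± 0.589 in sEVs and 9.29% ± 0.0549 in lEVs. For miR-16-5p the shares were 14.6% ± 0.554 and 17.1% ± 1.28, with the 3 lEVs shares above the 3 sEVs shares. None of these 4 most abundant miRNAs differed between the fractions at an adjusted p under 0.05 in edgeR. miR-126a-3p did in DESeq2 (adjusted p = 0.0200), and without lEVs replicate 1 edgeR called let-7c-5p (adjusted p = 3.13e-05), miR-126a-3p (0.00137) and miR-199a-3p/199b-3p (0.0176), each higher in sEVs. The fifth place was taken by miR-125b-5p in sEVs (72760 ± 4967 CPM) and by let-7b-5p in lEVs (60499 ± 26817 CPM). The 10 most abundant miRNAs of each library took 68.1% ± 1.41 of the sEVs counts and 66.4% ± 3.12 of the lEVs counts (SD, n = 3 each; exact two-sided permutation p = 0.5). After thinning every library to 47441 counts, 109.1 ± 0.993 miRNAs had at least 10 counts in sEVs and 112.4 ± 7.27 in lEVs (SD, n = 3 each; exact two-sided permutation p = 0.4). At least 3 counts were seen for 172.6 ± 5.39 miRNAs in sEVs and 187.7 ± 3.56 in lEVs (SD, n = 3 each; exact permutation p = 0.1). At least 1 count was seen for 215 ± 13.9 and 221 ± 23.6 miRNAs, where libraries are not comparable, since the table held no values of 1 and thinning makes them in all libraries but lEVs replicate 1. The smallest p that 3 against 3 libraries allow in such a test is 0.1.

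The only contrast of the design asks which miRNAs differ in abundance between small and large vesicles of bone. Vesicle size, the spin and the sucrose cushion differ together between the fractions, so their parts cannot be told apart. The closely related miR-125b-5p and miR-125a-5p made up 7.0% ± 0.468 and 3.89% ± 0.313 of the sEVs counts, against 3.23% ± 0.576 and 1.69% ± 0.0841 of the lEVs counts (SD, n = 3 each). Relative to lEVs, miR-125b-5p was 2.37-fold and miR-125a-5p 2.46-fold higher in sEVs. The largest differences among the 25 calls were those of miR-5126, 6.70-fold higher in sEVs, and miR-3473b/3473e, 4.47-fold higher in lEVs. miR-411-5p and both arms of miR-434, from the imprinted Dlk1-Dio3 locus, were also higher in sEVs. miR-191-5p and miR-29a-3p, a regulator of collagen messenger RNAs, were higher in lEVs. In all, 25 of the 145 miRNAs tested differed at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 12 higher in sEVs and 13 higher in lEVs. All 25 had their 3 values of one fraction above the 3 of the other, as had 64 of the 145 tested miRNAs, where chance gives a share of 10%. The 12 miRNAs higher in sEVs took 16.1%, 15.1% and 15.4% of the counts of sEVs replicates 1, 2 and 3, and 6.42%, 9.10% and 8.30% of those of lEVs replicates 1, 2 and 3. The count depended on single libraries: without lEVs replicate 1, which stood apart from the other lEVs libraries, 52 miRNAs passed (29 higher in sEVs and 23 in lEVs), the 25 included, and without lEVs replicate 3, 16 passed (8 in each direction). Scaling by library totals in place of TMM moved the median log2 fold change of the tested miRNAs from -0.04 to -0.18 and the split from 12 and 13 to 11 higher in sEVs and 24 higher in lEVs.

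**Figure D1:**
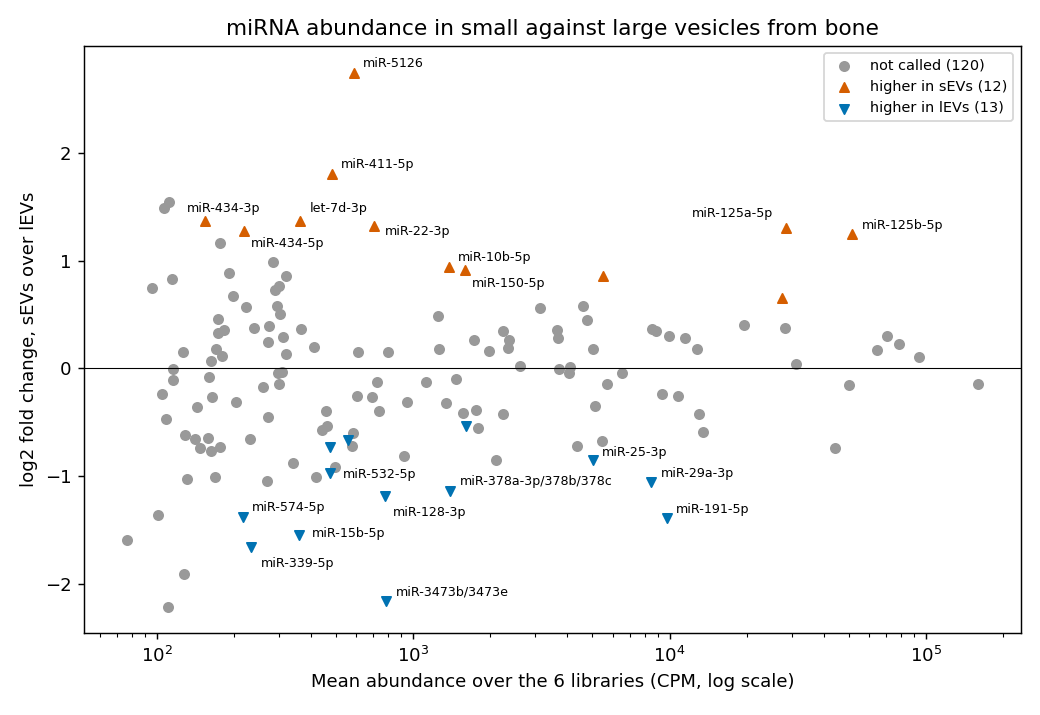
Log2 fold change of sEVs over lEVs (vertical axis) against the mean abundance over the 6 libraries in CPM (horizontal log axis), with 1 point for each of the 145 miRNAs tested. Upward triangles are the 12 miRNAs higher in sEVs and downward triangles the 13 higher in lEVs, from miR-5126 at 2.74 to miR-3473b/3473e at -2.16; grey circles are miRNAs not past the threshold.

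Among the miRNAs higher in sEVs, miR-5126 stood at 1003 ± 172 CPM in sEVs and 169 ± 92.5 CPM in lEVs (SD, n = 3 each; log2 fold change 2.74, SE 0.32; edgeR adjusted p = 0.00101). It had 87, 87 and 99 counts in sEVs replicates 1, 2 and 3 and 11, 10 and 14 in those of lEVs. Its hairpin lies at chromosome 1, 84695839 to 84695915 (GRCm38, plus strand), antisense to Dner, and shares a stretch of 20 bases with transcripts of 1 other gene, Nova2. The values of miR-411-5p, from chromosome 12, 109710175 to 109710256 between annotated genes, were 743 ± 62.2 and 221 ± 45.7 CPM (log2 fold change 1.81, SE 0.20; edgeR adjusted p = 0.000843). miR-125b-5p, with hairpins in noncoding host genes at chromosome 9, 41581926 to 41582002, and chromosome 16, 77646273 to 77646343, had 72760 ± 4967 and 30716 ± 697 CPM (log2 fold change 1.24, SE 0.12; edgeR adjusted p = 0.000534). miR-125a-5p, whose hairpin overlaps an exon of Spaca6 at chromosome 17, 17830812 to 17830879, had 40472 ± 3375 and 16460 ± 3552 CPM (log2 fold change 1.30, SE 0.17; edgeR adjusted p = 0.00184). miR-22-3p, miR-10b-5p, encoded in the Hoxd cluster, and the lymphocyte miRNA miR-150-5p were higher in sEVs by log2 fold changes of 1.32, 0.94 and 0.91 (edgeR adjusted p = 0.00268, 0.00367 and 0.00268). The passenger strand let-7d-3p had a log2 fold change of 1.37 (SE 0.33; edgeR adjusted p = 0.0225). It missed the threshold without lEVs replicate 2 (adjusted p = 0.0751), lEVs replicate 3 (0.0930), sEVs replicate 1 (0.0526) or sEVs replicate 2 (0.0917).

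Among the miRNAs higher in lEVs, the joined row miR-3473b/3473e stood at 1290 ± 37.9 CPM in lEVs and 285 ± 49.6 CPM in sEVs (SD, n = 3 each; log2 fold change -2.16, SE 0.17; edgeR adjusted p = 0.000284). Its hairpins lie at chromosome 10, 41670739 to 41670793, antisense to Ccdc162, and in an intron of Rbks at chromosome 5, 31667231 to 31667340. They share 20-base stretches with transcripts of 752 other genes. The most abundant was miR-191-5p, at chromosome 9, 108568319 to 108568392, with 14209 ± 1166 CPM in lEVs and 5407 ± 752 CPM in sEVs (log2 fold change -1.39, SE 0.15; edgeR adjusted p = 0.000843). miR-29a-3p had 11499 ± 2398 CPM in lEVs and 5503 ± 659 CPM in sEVs (log2 fold change -1.06, SE 0.18; edgeR adjusted p = 0.00447). miR-15b-5p, miR-128-3p and the joined row miR-378a-3p/378b/378c, which includes the miRNA of a Ppargc1b intron, were 2.93-fold, 2.27-fold and 2.20-fold higher in lEVs (edgeR adjusted p = 0.00191, 0.00101 and 0.00191). miR-339-5p and miR-25-3p were 3.15-fold and 1.80-fold higher in lEVs (edgeR adjusted p = 0.0154 and 0.00617). The counts of miR-339-5p were low, with 18, 39 and 26 in lEVs and 11, 6 and 13 in sEVs. miR-574-5p, whose hairpin shares 20-base stretches with transcripts of 46 other genes, was 2.60-fold higher (edgeR adjusted p = 0.0225). It missed the threshold without lEVs replicate 3 (adjusted p = 0.0700), sEVs replicate 1 (0.0732) or sEVs replicate 3 (0.0629). miR-532-5p was 1.96-fold higher (edgeR adjusted p = 0.0159), and missed the threshold without lEVs replicate 3 (adjusted p = 0.0805). DESeq2 called neither of these last 2 (adjusted p = 0.0999 and 0.109). The 4 other called miRNAs lie outside the naming rule and were named after their values were seen. miR-23a-3p/23b-3p was higher in sEVs (log2 fold change 0.86; edgeR adjusted p = 0.00263), and miR-425-5p (-0.73; 0.0159), miR-744-5p (-0.66; 0.0469) and miR-322-5p (-0.53; 0.0477) were higher in lEVs. The last 3 missed the threshold in DESeq2 (adjusted p = 0.223, 0.261 and 0.183), without lEVs replicate 2 (0.0712, 0.0991 and 0.0991) and without lEVs replicate 3 (0.0628, 0.0930 and 0.134). miR-744-5p also missed it after thinning (adjusted p = 0.232) and without sEVs replicate 2 (0.110) or 3 (0.0950). miR-322-5p also missed it with library totals (adjusted p = 0.0536) and without sEVs replicate 1 (0.146) or 2 (0.125).

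**Figure D2:**
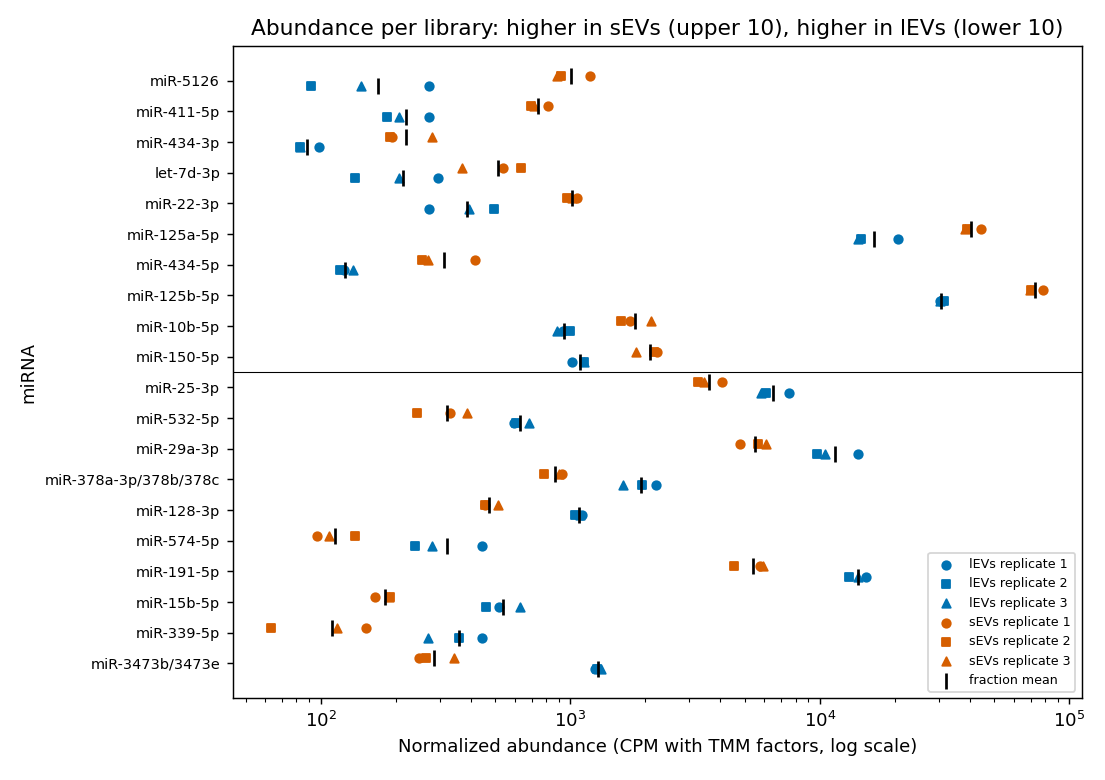
Abundance in CPM with TMM factors (horizontal log axis) of the 10 miRNAs with the largest rise in sEVs and the 10 with the largest fall, with 1 symbol per library (blue for lEVs, orange for sEVs, shapes for replicates) and a black bar at each fraction's mean. The 3 values of one fraction lie above the 3 of the other in every row, as for miR-125b-5p, with means of 72760 CPM in sEVs and 30716 CPM in lEVs.

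Of the 16 miRNA lists, the only one past camera's threshold with its preset correlation was the imprinted Dlk1-Dio3 cluster on chromosome 12, whose miRNAs are expressed from the maternal copy. All 7 of its tested miRNAs had log2 fold changes above 0, with a median of 0.77 (camera with Benjamini-Hochberg adjustment over 11 lists, adjusted p = 0.0218). That call was lost with an estimated correlation between miRNAs (adjusted p = 0.654 with an estimated correlation). Of the 7, 3 rose in sEVs, miR-411-5p, miR-434-3p and miR-434-5p, and 4 did not pass. When adjusted over the list alone, 5 rose. miR-434-3p and miR-434-5p, the arms of a hairpin at chromosome 12, 109594506 to 109594599, antisense to Rtl1, had log2 fold changes of 1.37 (SE 0.32) and 1.27 (SE 0.30; edgeR adjusted p = 0.0211 for each). Both arms rested on few counts. In replicates 1, 2 and 3, miR-434-3p had 4, 9 and 8 counts in lEVs and 14, 18 and 31 in sEVs. For miR-434-5p these were 5, 13 and 13 in lEVs and 30, 24 and 30 in sEVs. The log2 fold changes of miR-127-3p, miR-382-5p and miR-379-5p were 0.49, 0.77 and 0.15 (edgeR adjusted p = 0.0538, 0.135 and 0.509). The cluster took 0.470% ± 0.0105 of the sEVs counts and 0.309% ± 0.0383 of the lEVs counts (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). The list test was also lost without lEVs replicate 1 (adjusted p = 0.117, with 6 of 7 members called) and without lEVs replicate 2 (adjusted p = 0.0770, with 1 of 7 called). It held without lEVs replicate 3 (adjusted p = 0.0471), where 1 of 7 was called. The call of miR-434-3p was lost without lEVs replicate 2 (adjusted p = 0.0989), lEVs replicate 3 (0.108) or sEVs replicate 3 (0.103). That of miR-434-5p was lost without lEVs replicate 2 (adjusted p = 0.0822) or lEVs replicate 3 (0.0900). DESeq2 called neither arm (adjusted p = 0.204 and 0.146), and 1 of 15 members in all. miR-127-3p passed with a mean of at least 100 CPM (adjusted p = 0.0469) and with zeros read as 1 (0.0417).

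**Figure D3:**
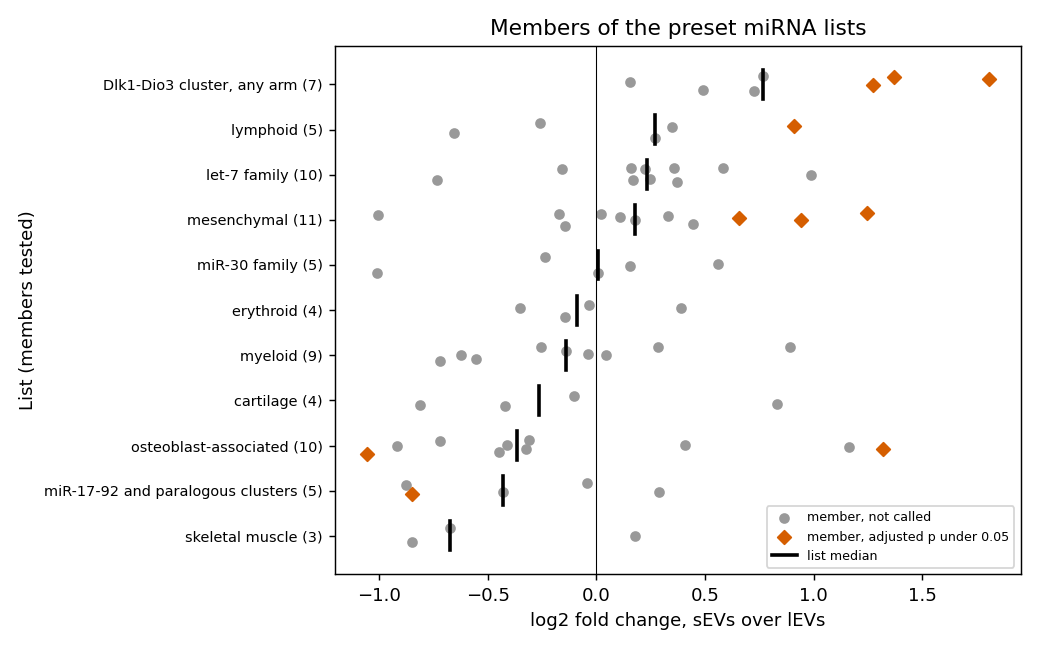
Log2 fold change of sEVs over lEVs (horizontal axis) for the tested members of the 11 miRNA lists with at least 3 of them (vertical axis, number of tested members in brackets; points are spread vertically for legibility). Orange diamonds are members past the threshold, grey circles the others and black bars list medians, from 0.77 for the Dlk1-Dio3 cluster to -0.67 for the skeletal muscle list.

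Of 11 tested miRNAs typical of mesenchymal cells, 3 rose in sEVs, miR-125b-5p, miR-10b-5p and miR-143-3p, none fell and 8 did not pass (camera adjusted p = 0.252; 4 rose and 1 fell when adjusted over the list alone). Log2 fold changes were above 0 for 8 of the 11, with a median of 0.18, and fry, which asks whether a list's members move on balance one way, gave an adjusted p of 0.00111. miR-143-3p, abundant in smooth muscle and fibroblasts, had 33575 ± 3729 CPM in sEVs and 21305 ± 3285 CPM in lEVs (SD, n = 3 each; log2 fold change 0.65, SE 0.16; edgeR adjusted p = 0.0231). It missed the threshold when scaled by library totals (adjusted p = 0.109) and without lEVs replicate 3 (0.102), sEVs replicate 2 (0.125) or sEVs replicate 3 (0.120). The mesenchymal list took 20.8% ± 0.477 of the sEVs counts and 15.9% ± 1.44 of the lEVs counts (SD, n = 3 each; exact two-sided permutation p = 0.1). Most of this difference lay in miR-125b-5p, with 7.0% in sEVs and 3.23% in lEVs. miR-143-3p took 3.23% and 2.27%, and the largest member, miR-199a-3p/199b-3p, 9.36% and 9.29%. The list share is therefore not separate support beside the call of miR-125b-5p. Of 10 osteoblast-associated miRNAs, miR-22-3p rose and miR-29a-3p fell in sEVs and 8 did not pass (camera adjusted p = 0.935; 2 rose and 1 fell when adjusted over the list alone). miR-26a-5p had a log2 fold change of 0.41 (edgeR adjusted p = 0.0537). It passed in DESeq2 (adjusted p = 0.00606), limma voom (0.0375), after thinning (0.0450), without the 5 most abundant miRNAs (0.0379) and with zeros read as 1 (0.0456). Neither endothelial miRNA passed, with log2 fold changes of 0.30 for miR-126a-3p and 0.37 for miR-126a-5p (edgeR adjusted p = 0.126 and 0.131). Both passed when adjusted over the list alone. None of the 4 cartilage miRNAs passed (camera adjusted p = 0.935; 0 when adjusted over the list alone). miR-140-3p and miR-140-5p had log2 fold changes of -0.42 and -0.81, and lEVs replicate 1 lay above the mean of the other lEVs libraries by log2 values of 0.94 and 1.02. None of the 3 skeletal muscle miRNAs passed (camera adjusted p = 0.859; 1 fell when adjusted over the list alone), with -0.85 for miR-133a-3p/133b-3p (edgeR adjusted p = 0.0555). The list members miR-145a-5p, miR-29b-3p, let-7a-5p, let-7e-5p/7k, let-7j and miR-30b-5p lie outside the naming rule and were named after their values were seen. With library totals, edgeR called miR-145a-5p, miR-29b-3p, miR-140-5p and miR-206-3p higher in lEVs (adjusted p = 0.0441, 0.0441, 0.0368 and 0.0432). Without the filter on low counts, 1 of 14 mesenchymal, 4 of 16 osteoblast-associated, 1 of 4 cartilage and 2 of 4 muscle miRNAs fell. miR-199a-5p rose in DESeq2 and after thinning (adjusted p = 0.0267 and 0.0493), miR-145a-5p fell in limma voom (0.0497) and miR-133a-3p/133b-3p after thinning (0.0450). In CPM with TMM factors, lEVs replicate 1 differed from the mean of the other lEVs libraries by a median log2 value of 0.67 over the cartilage list and -0.61 over the skeletal muscle list. Without it, 1 of the 3 muscle miRNAs fell, 5 of 12 mesenchymal miRNAs rose and 1 fell, 2 of 11 osteoblast-associated miRNAs rose and 2 fell, and 1 of the 2 endothelial miRNAs rose. The median log2 fold change then moved from -0.67 to -0.25 for the skeletal muscle list and from -0.26 to -0.04 for the cartilage list. Without lEVs replicate 2, 1 of 3 muscle and 1 of 4 cartilage miRNAs fell. Without sEVs replicate 1, 1 of 12 mesenchymal miRNAs fell, and without sEVs replicate 3, 3 of 11 osteoblast-associated miRNAs fell.

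Of 5 lymphoid miRNAs among those of blood cells, miR-150-5p rose in sEVs (2081 ± 211 against 1096 ± 71.7 CPM; SD, n = 3 each) and 4 did not pass, with 1 rising when adjusted over the list alone (camera adjusted p = 0.603). None of 9 myeloid miRNAs passed (camera adjusted p = 0.935; 0 when adjusted over the list alone). With library totals 1 of 9 fell, without the filter on low counts 2 of 10 fell, and after thinning 1 of 8 rose. The granulocyte and monocyte miRNA miR-223-3p stood at 31631 ± 1110 CPM in sEVs and 30676 ± 423 CPM in lEVs (SD, n = 3 each; log2 fold change 0.04, SE 0.11), and its sign turned when scaled by library totals. None of 4 erythroid miRNAs passed (camera adjusted p = 0.974; 0 when adjusted over the list alone). The erythroid list, which holds miR-16-5p, took 15.1% ± 0.544 of the sEVs counts and 17.8% ± 1.37 of the lEVs counts (SD, n = 3 each; exact two-sided permutation p = 0.1). Nearly all of this was miR-16-5p, with 14.6% in sEVs and 17.1% in lEVs, against 0.431% and 0.579% for miR-486a-5p/486b-5p. miR-451a, a red blood cell miRNA, had 320 ± 98.8 and 228 ± 99.6 CPM. Without lEVs replicate 1, whose median log2 difference from the other lEVs libraries was -0.34 over the myeloid list, 2 of the 9 myeloid miRNAs fell and 2 of the 5 lymphoid miRNAs rose.

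Of 10 let-7 miRNAs, near-identical sequences whose reads may be hard to assign, none passed in edgeR, also when adjusted over the list alone (camera adjusted p = 0.603). DESeq2 called let-7a-5p and let-7e-5p/7k higher in sEVs (adjusted p = 0.0170 and 0.0267) and let-7i-5p higher in lEVs (0.0188). In edgeR, 2 rose and 1 fell without the filter on low counts, 1 rose and 1 fell after thinning, and let-7i-5p fell with library totals (adjusted p = 0.00713). limma voom called let-7j higher in sEVs (adjusted p = 0.0342). The family held 26.7% ± 0.627 of the sEVs counts and 27.8% ± 3.57 of the lEVs counts (SD, n = 3 each). In CPM with TMM factors, lEVs replicate 1 lay above the other lEVs libraries by a median log2 value of 0.56 over this family. Without it, 5 of the 10 rose, 1 fell and 4 did not pass. Without lEVs replicate 2, 1 of the 10 fell. The 1 tested let-7 passenger strand, let-7d-3p, rose. Adjusting over this list alone leaves its p unadjusted and adds no support. None of 5 miR-30 miRNAs passed (camera adjusted p = 0.974, with a median of 0.01 and a mean of -0.10; 1 rose and 1 fell when adjusted over the list alone). miR-30e-5p had a log2 fold change of 0.56 (edgeR adjusted p = 0.0503). It passed in limma voom (adjusted p = 0.0375), without the filter on low counts (0.0349), with a mean of at least 100 CPM (0.0326), after thinning (0.0289) and with zeros read as 1 (0.0293). miR-30b-5p fell with library totals (adjusted p = 0.0441) and without the 5 most abundant miRNAs (0.0499). Of 5 miRNAs of the growth-promoting miR-17-92 and paralogous clusters, miR-25-3p fell in sEVs and 4 did not pass, with 1 falling when adjusted over the list alone (camera adjusted p = 0.603). With library totals 2 of these 5 fell, and without the filter 2 of 11. Without lEVs replicate 1, 2 of these 5 fell, 1 of the 5 miR-30 miRNAs rose and 1 fell, and the 1 tested epithelial miRNA rose. In the lists with fewer than 3 tested members, the neuron-enriched miR-128-3p fell and miR-7a-5p did not pass. Neither miR-192-5p and miR-194-5p of liver and kidney nor the epithelial miR-203-3p passed (log2 fold change 0.86; edgeR adjusted p = 0.0542); the last passed with zeros read as 1 (adjusted p = 0.0456). When adjusted over the list alone, 1 neural miRNA fell, 1 epithelial miRNA rose and 0 of liver and kidney passed. The epithelial list had 1 tested member, so its edgeR p of 0.0116 is then unadjusted. By fry, which does not compare a list with other miRNAs, the mesenchymal, miR-17-92 and Dlk1-Dio3 lists passed (adjusted p = 0.00111, 0.0163 and 0.0163).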

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

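The alternative that read every 0 as 1 count and those of the ratios between miRNAs were chosen after seeing the data. The count of 25 miRNAs stayed within 1.5 times in every setting except 3. Without the filter on low counts, 53 of 327 miRNAs were called, 20 higher in sEVs and 33 in lEVs, the 25 included. Leaving out 1 library gave between 16 and 52 calls, 8 to 29 higher in sEVs and 8 to 23 in lEVs. The high came without lEVs replicate 1, where the coefficient of variation fell from 0.177 to 0.0832, and the low without lEVs replicate 3. Library totals kept the count near the main one (35), but 24 were higher in lEVs against 13. Leaving out the TMM factors moved the median log2 fold change from -0.04 to -0.18, a shift toward lEVs that goes with this split. Why the TMM factors differ between libraries was not tested. DESeq2 called 29 miRNAs and kept 18 of the 25, and limma voom called 29 and kept 25. Of the 21 named miRNAs that were called, 15 kept their direction and call in every setting. Deviations from the fraction means correlated at 0.00, 0.06 and 0.37 for replicate numbers 1, 2 and 3. Only number 3 correlated best with its own number in both fractions. This cannot decide whether equal numbers pair the libraries. Deviations among 3 libraries depend on each other, and lEVs replicate 1, which stood apart, weighed on the lEVs mean. With the number as a replicate block, 26 miRNAs were called, 23 of the 25 among them, without miR-434-3p (adjusted p = 0.0636) and miR-322-5p (0.0599), and with let-7e-5p/7k (0.0399), miR-30e-5p (0.0359) and miR-133a-3p/133b-3p (0.0428). Of the 4 called miRNAs outside the naming rule, miR-744-5p and miR-322-5p also missed the threshold with DESeq2 size factors in edgeR (adjusted p = 0.0505 and 0.0569), a mean of at least 100 CPM (0.0579 and 0.0556) and zeros read as 1 (0.0561 and 0.0527). One list was called by camera, 0 with an estimated correlation, and between 0 and 1 when 1 library was left out, with 0 without lEVs replicate 1 or 2. The difference in miRNAs with at least 10 counts (sEVs minus lEVs) turned from -3.27 to 11.3 without thinning, where lEVs replicate 1 had the fewest counts, and that in the share of the most abundant miRNAs turned from 1.76 percentage points for 10 miRNAs to -0.416 for 5; neither difference passed its test. Other turns of direction were of log2 fold changes near 0, none of them called in either setting, and the cause was not tested. With library totals, miR-223-3p stood at -0.084, miR-30a-5p at -0.12, miR-30c-5p at -0.0034 and miR-194-5p at -0.088. miR-30a-5p stood at -0.018 without the filter and at -0.0031 without the 5 most abundant miRNAs, miR-93-5p at 0.010 after thinning, and miR-15a-5p at 0.0062 with the replicate block and 0.0021 with zeros read as 1. With the replicate block, camera's direction turned for the erythroid list and the miR-30 family, while the medians kept their sign (-0.055 against -0.089 and 0.0086 against 0.0091). Leaving out 1 library gave log2 fold changes from -0.31 to 0.075 for miR-16-5p, -0.014 to 0.25 for miR-199a-3p/199b-3p, -0.049 to 0.59 for let-7b-5p, -0.58 to 0.016 for miR-486a-5p/486b-5p, and -0.21 to 0.22 for miR-15a-5p. The ranges were -0.030 to 0.077 for miR-223-3p, -0.0018 to 0.33 for miR-1a-3p, -0.33 to 0.12 for miR-455-5p, -0.11 to 0.12 for miR-30a-5p, and -0.11 to 0.19 for miR-194-5p. List medians ranged from -0.21 to 0.046 for the erythroid list and from -0.11 to 0.12 for the miR-30 family. Of the ratios between miRNAs, 2 arm and 6 neighbour pairs differed; with library totals 2 and 7 did, with a pseudocount of 1 CPM 2 and 7, and without 1 library 0 to 2 and 3 to 8. With these depths, dispersions and 3 libraries per fraction, simulated 1.5-fold changes were called in 35% of cases. Thinning to the shallowest library left 112 miRNAs to test, with 30 called; the part of depth alone was not separated.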

Other observations

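Tests of the splits, of the depth and label of lEVs replicate 1, and of ratios between arms and between neighbouring miRNAs, with their alternatives, were chosen after the result was seen; those of base composition, shared sequence and scaling were chosen before. miRNAs outside the naming rule were named after their values were seen. Leaving out lEVs replicate 1 brought 27 further calls by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the let-7 family, let-7a-5p (log2 fold change 0.53, adjusted p = 0.000181), let-7b-5p (0.59, 6.57e-05), let-7c-5p (0.58, 3.13e-05), let-7e-5p/7k (0.82, 0.000119) and let-7j (1.43, 0.00146) were then higher in sEVs, and let-7i-5p was higher in lEVs (-0.37, 0.00680). The endothelial miR-126a-3p (0.38, 0.00137), and miR-199a-5p (0.58, 0.00137), miR-26a-5p (0.44, 0.00207) and miR-27a-3p/27b-3p (0.54, 0.00137) were higher in sEVs. The muscle miRNA miR-133a-3p/133b-3p (-1.08, 2.37e-05) was higher in lEVs, as were miR-29b-3p (-0.90, 0.0127), miR-145a-5p (-1.10, 0.00448) and miR-103-3p/107-3p (-0.67, 0.00175). None of these were among the 25 calls, though with all 6 libraries some passed in edgeR after thinning, with library totals or without the filter on low counts.

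The real split of the libraries gave 25 calls and the highest other split 1, so that 1 of the 10 splits gave as many; 10 splits are too few for a share under 0.05.

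lEVs replicate 1 differed from the other lEVs libraries in counts of many miRNAs. In CPM with TMM factors, it had more miR-148a-3p (log2 difference 1.27), let-7b-5p (1.02) and miR-16-5p (0.60) and less miR-19b-3p (-1.43) and miR-21a-5p (-0.78). These values depend on the scaling. As shares of the totals of lEVs replicates 1, 2 and 3, let-7b-5p held 7.80%, 5.14% and 5.19%. The shares of miR-16-5p were 18.5%, 15.9% and 16.9%, and those of miR-21a-5p 0.599%, 1.45% and 1.31%. Low depth alone is argued against for lEVs replicate 1, since at one depth its chi-square over degrees of freedom against replicate 2 was 12.89 times that of replicate 2 against 3. A mislabelled sEVs library is argued against as well: over 51 of the 52 miRNAs called without it (1 was not tested with all 6 libraries), its median position between the other lEVs (0) and the sEVs (1) was 0.173 (bootstrap 95% interval -0.03 to 0.33). A base composition trend may be part of it, as its difference correlated across 139 miRNAs with the GC content of the hairpin arm region (Spearman rho 0.29, permutation p = 0.000470; miRNAs are not independent replicates). A difference in the preparation or the animals stays open and was not tested.

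Of 17 pairs of miRNAs within 10 kb, 12 had log2 fold changes of the same sign (Spearman rho 0.46 across pairs, permutation p = 0.0611). Several pairs share a miRNA or a hairpin, and this p treats them as independent, which they are not. Ratios differed between the fractions for 6 of the 17 pairs (limma, Benjamini-Hochberg). Of the 6, 5 held a called miRNA and shared no 20-base stretch with other transcripts, against a mix of source cells that differ only in transcribing each cluster as the whole cause, though it may contribute. The ratios of miR-379-5p over miR-411-5p (log2 difference -1.59, limma adjusted p = 0.00132), miR-99b-5p over miR-125a-5p (-1.13, 0.00315) and, from the same hairpins, miR-99b-3p over miR-125a-5p (-2.05, 0.00315) kept their call with library totals, a pseudocount of 1 CPM and each library left out in turn. Those of miR-145a-5p over miR-143-3p (-1.62, 0.0249) and miR-191-5p over miR-425-5p (-0.69, 0.0390) lost it with each library left out except sEVs replicate 1 (limma adjusted p = 0.0513 to 0.127). miR-191-5p and miR-425-5p were both called higher in lEVs, while miR-143-3p was called higher in sEVs and miR-145a-5p was not called. A different output of the hairpin alone stays open, since 0 arm pairs with a called miRNA and no shared stretch differed. Of 17 arm pairs, 4 held a called miRNA, and those of miR-574 and miR-125b had a shared stretch. For miR-125b this was with Gm28119, the host of 1 copy of its hairpin, so its exclusion says little about unrelated transcripts. Its ratio did not pass either (log2 difference 0.88, limma adjusted p = 0.276). Setting both pairs aside left let-7d-5p over let-7d-3p (log2 difference -1.09, limma adjusted p = 0.0802) and miR-434-5p over miR-434-3p (-0.0013, 0.997), too few to decide. Of the arm pairs whose ratio differed, miR-574-5p over miR-574-3p (-1.68, 0.0160) shares stretches with 46 other genes. The other, miR-361-5p over miR-361-3p (1.49, 0.0282), has no called arm. Both lost the call without lEVs replicate 1 (limma adjusted p = 0.0561 and 0.0613), sEVs replicate 1 (0.0676 and 0.0970) or sEVs replicate 3 (0.0979 each). The miR-361 pair also lost it without lEVs replicate 3 (0.0617). Selective loading or stability of single miRNAs, or source cells that process clusters differently, may account for the neighbour ratios as hypotheses. Neither was tested, nor was the part of the spins and the sucrose cushion, which differ between the fractions.

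The largest changes among the 25 calls were those of miR-5126 and miR-3473b/3473e. The scaling of the libraries is argued against, since both kept their direction with adjusted p of at most 0.000789 over library totals, DESeq2 size factors and leaving out the 5 most abundant miRNAs. Reads shared with other transcripts may contribute: the hairpins of miR-3473b/3473e share 20-base stretches with 752 other genes and that of miR-5126 with 1, Nova2. Of the 145 tested miRNAs, 27 share any. That count includes miRNAs matched only by the host gene of another copy of their hairpin, such as miR-92a-3p with Mir17hg and miR-24-3p with 2010111I01Rik. It therefore overstates sharing with unrelated genes. Fragments of such transcripts, more of them in one fraction, stay open as a candidate source, as does a difference in the miRNAs themselves.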
